A study of Homo sapiens with 6 samples.

How the data were processed

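Total RNA of MDA-MB-231 cells, from 3 samples labelled as control and 3 as NR1D1 knockout, was copied to cDNA with a whole-transcript amplification kit and biotin-labelled for GeneChip arrays, per the labels' protocols. The authors deposited 1 table of values per array, which lie between 1.16 and 13.75 and were read as log2 probe set summaries from that range. The 6 arrays share nearly the same quantiles, with medians of 5.18 to 5.22, so the deposited values had been normalized between arrays. Scanner software, background correction, normalization and summarization are not given in the sources used here, and the values were used as deposited. An error in that scale would change every fold given. No detection calls were at hand, so a dim probe set was neither removed nor called absent, and the floor of the array can make the fold of a dim gene too small.

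Probe sets were named through a table of the platform's annotation. Of 53617 probe sets, 16098 had 1 gene symbol, none had several and 37519 had none in that table, which leaves them unnamed here. Symbols were checked through gene identifiers against a RefSeq gene table of assembly GRCh38.p14, where all 16098 matched and 0 symbols needed updating. That table served for names, gene classes and the order of genes only, since no genome build is named for the arrays. Where several probe sets shared a symbol (779 genes) the one with the highest mean over all arrays was used, which left 14884 genes, 11916 of them protein-coding. No gene was filtered out for a low level.

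The control and knockout groups, 3 arrays each, were taken from the labels. They were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, two-sided) on the log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Changes of 2-fold or more were also counted. Before the data were examined, 28 gene lists were fixed, of which 6 fit the treatment and the gene (interferon-stimulated genes, DNA sensing, chemokines and cytokines, circadian clock, antioxidant and DNA repair genes) and the others cover further pathways and markers of other cell types. A list was tested with camera at its preset correlation of 0.01, adjusted over the 27 lists with at least 5 measured members. The list of mitochondrially encoded genes had 0 measured members and was not tested. Calls in a list were counted over all genes and adjusted over the list alone, and camera with an estimated correlation and fry were run as alternatives. With 3 arrays a group, an estimated correlation leaves camera little power. A miss with it does not show that a list was unchanged.

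The genes named in the text were chosen by a rule set beforehand. It takes NR1D1, NR1D2 and the genes next to NR1D1, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, and from each list up to 4 called members with the largest change, or up to 2 with the smallest p where none was called. Symbols of non-coding RNAs were left out of the top genes, which concerned 1 fall and 0 rises. The text and the figure leave out 1 of the 10 largest rises. The rule allows genes of lists that are only summarised to be left out. Genes outside the rule are named as such where they appear.

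Protein-coding genes were also put in genome order to ask whether neighbours changed together. Means of 20 consecutive genes on a chromosome were compared with 1000 shuffled orders, on the log2 changes as fitted and on changes bounded at 2-fold, and windows beyond the 95th percentile of the shuffled maxima were merged into stretches. Whole chromosomes were tested as lists with camera. This step was not among the choices fixed beforehand.

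The fit was tested on simulated data with the means and spreads of these 14884 genes, with 200 changed genes in each of 5 runs. It called 41.79% of genes changed by 0.5 on the log2 scale, 91.04% of those changed by 1 and 98.48% of those changed by 2, and 3.75% of its calls were unchanged genes. The data gave 1412 calls, and fewer changed genes make the adjustment stricter, so these rates need not hold for this comparison. A list shifted by -0.5 was called in 50 of 50 runs, and 2 of 1300 unchanged lists were called. Each gene was simulated independently of the others. These runs therefore do not show how often camera calls an unchanged list whose genes vary together. Alternatives were another quantile normalization, centring on array medians, leaving out the dimmest 25% or 50% of genes, averaging probe sets or testing each one, a prior with trend and robust settings, array weights, a block for the replicate number, leaving out each array, a fold threshold of 1.5 with an unadjusted p, limma's treat against 1.2-fold, and leaving out genes in stretches of neighbours that changed together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.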

Results

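Gene expression was measured on GeneChip whole-transcript arrays in MDA-MB-231 cells, an established human triple-negative breast carcinoma line, after 72 h in medium with 200 µM hydrogen peroxide. Control cells and cells with a knockout of NR1D1, which encodes the heme-binding nuclear receptor and circadian repressor REV-ERBα, gave 3 arrays each, 6 in all. The titles call the arrays of a group biological replicates, but nothing in the labels says that they came from separate cultures or from separate knockout clones, so the p-values measure the spread between these arrays, which may in part be technical. The comparison asks which transcripts differ between NR1D1 knockout and control cells when both are under oxidative stress. All 6 arrays were treated, so it cannot separate a difference in the response to peroxide from one that was there before it. The deposited log2 values covered 53617 probe sets per array, with array medians between 5.18 and 5.22, and 14884 genes could be tested by name. The number of arrays limits the precision, and the median standard error of a log2 change was 0.101.

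No probe set carried the name of NR1D1 in the probe annotation used here, so the level of the targeted gene is not reported and the knockout could not be checked from its transcript. The same held for its paralog NR1D2 and its neighbour THRA. Of the other genes next to NR1D1, MED24 measured 9.03 ± 0.026 in control and 9.18 ± 0.075 in knockout arrays (log2, mean ± SD, n = 3 each), with a limma adjusted p of 0.301. CASC3 differed by 0.14 on the log2 scale (adjusted p = 0.46) and MSL1 by 0.058 (adjusted p = 0.849).

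Knockout cells had far lower levels of several inflammatory transcripts, such as CXCL8, C3 and IL24, and higher levels of genes such as ENPP4, NEO1 and DSG2. The transcript of CXCL8, the neutrophil chemoattractant interleukin 8, stood at 8.38 ± 0.082 in control and 4.21 ± 0.081 in knockout arrays (log2, mean ± SD, n = 3 each), which is 18-fold lower (limma, adjusted p = 2.59e-07). SRGN, the proteoglycan serglycin of secretory granules, was 6.96-fold lower, C3, the central complement component, 5.29-fold lower and IL24, a cytokine of the interleukin 10 family, 5.15-fold lower. The lysosomal protease gene CTSS was 4.62-fold lower, the hyaluronan-degrading CEMIP 4.15-fold lower, COXFA4L3 3.66-fold lower, the cell-surface peptidase gene DPP4 3.63-fold lower and the leukocyte adhesion receptor gene ICAM1 3.57-fold lower. These 9 genes and PDE4DIP had the largest falls among named coding genes, with adjusted p no higher than 0.000238. PDE4DIP was 3.5-fold lower at its brightest probe set, but near-identical copies of this gene make its value uncertain, and its 6 probe sets changed by between -1.81 and -0.75 on the log2 scale.

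The largest rise belonged to ENPP4, an ecto-phosphodiesterase gene, from 5.33 ± 0.26 to 7.86 ± 0.275 (log2, mean ± SD, n = 3 each), or 5.77-fold (limma, adjusted p = 0.000114). NEO1, which encodes the netrin receptor neogenin, rose 5.36-fold, CACHD1, related to calcium channel subunits, 5.18-fold and the lysophospholipid acyltransferase gene MBOAT1 4.99-fold. ACSS3, a mitochondrial short-chain acyl-CoA synthetase gene, rose 4.54-fold and the ceramide synthase gene CERS6 3.65-fold. DSG2, a desmosomal cadherin gene, rose 3.63-fold and was nearly identical on the 3 knockout arrays (10.09 ± 0.0047, against 8.23 ± 0.07 in control). SESN3, a stress-responsive sestrin gene, rose 3.12-fold and NLGN1, the synaptic adhesion gene neuroligin 1, 3.11-fold (adjusted p = 0.0026, the highest among these 9 rises).

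**Figure D1:**
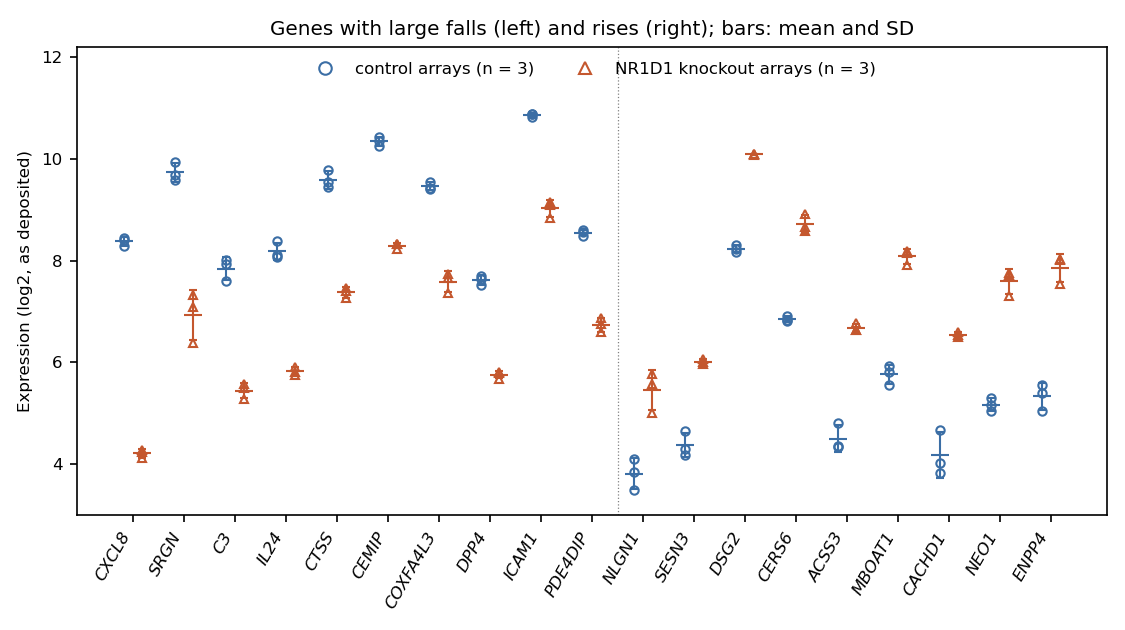
Log2 expression (y axis, as deposited) of the 10 coding genes with the largest falls and of 9 of the 10 with the largest rises, for each control array (circles) and each NR1D1 knockout array (triangles), with group means and SD (bars, n = 3 each). No gene shown has overlapping groups, and CXCL8 spans the widest gap, from 8.38 to 4.21.

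In all, 1412 of 14884 genes passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 706 of them higher and 706 lower in the knockout. Of these, 142 changed by 2-fold or more, 51 higher and 91 lower. By gene class, 671 protein-coding genes were higher and 655 lower, 21 and 23 long non-coding RNAs, and 9 and 15 microRNA genes. The 3 values of each group did not overlap for 28.7% of genes, where chance gives 10%. The first principal component held 51.1% of the variance and separated the groups, and arrays correlated at 0.985 to 0.9879 within and 0.9803 to 0.9835 between groups. The count of changed genes was 789 without control replicate 1 (338 higher and 451 lower), 859 without control replicate 2 (431 and 428), 723 without control replicate 3 (336 and 387) and 813 without knockout replicate 2 (356 and 457).

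Genes of the NF-κB pathway and of cytokines were lower as lists. Of 10 measured genes of the NF-κB pathway, made up of its subunits, regulators and targets, 8 fell and none rose, with the same 8 when adjusted over the list alone. Besides ICAM1 these included the signalling adaptor gene TRAF1 (2.43-fold lower), the subunit gene NFKB1 (2.04-fold lower, from 9.22 ± 0.0955 to 8.19 ± 0.0836, n = 3 each) and TNIP1, whose product restrains the pathway (2.03-fold lower). The median log2 change of the list was -0.82. TRAF1 lies on chromosome 9 among 58 neighbouring genes of which 48 measured above 0 on the log2 scale of change, so it moved against its neighbours. Of 22 chemokine and cytokine genes 10 fell and none rose, and 12 fell and 1 rose when adjusted over the list alone. Without knockout replicate 2 the falls were 6. CSF1, the macrophage growth factor gene, fell from 10.01 ± 0.0356 to 8.26 ± 0.0381 (n = 3 each), and the interferon-induced chemokine gene CXCL11 was 1.7-fold lower. CSF1 lies on chromosome 1 within 98 neighbouring genes of which 82 measured below 0, with a median log2 change of -0.26. The camera adjusted p was 8.27e-10 for the NF-κB pathway and 6.89e-09 for cytokines. These were the 2 list calls that held with an estimated correlation between genes, each at an adjusted p = 0.0345.

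Genes of cell division were higher. All 27 measured mitosis genes had a positive log2 change and 18 of them rose, or 24 when adjusted over the list alone, with a median log2 change of 0.38. The rises were 7 without control replicate 1, 8 without control replicate 3, 9 without knockout replicate 2 and 11 without knockout replicate 3. The mitotic kinesin gene KIF20A rose 1.72-fold, from 8.43 ± 0.0818 to 9.21 ± 0.0496 (n = 3 each), CCNB2, which encodes cyclin B2, 1.5-fold, CDC20, an activator of the anaphase-promoting complex, 1.48-fold and the centromeric histone gene CENPA 1.48-fold. Of 24 DNA replication genes 11 rose and none fell, or 18 and none when adjusted over the list alone. They included GINS2, of the replicative helicase (2.03-fold higher), MCM3 (1.5-fold higher), the thymidylate synthase gene TYMS (1.52-fold higher) and GINS4 (1.49-fold higher). A second, dimmer probe set of GINS4 changed by only 0.0803 on the log2 scale. Both lists were higher by camera with its preset correlation, at adjusted p of 3.26e-14 and 3.89e-09. With an estimated correlation neither passed (adjusted p = 0.185 for mitosis and adjusted p = 0.159 for replication). Without control replicate 1 or 3 or knockout replicate 2 or 3, CCNB2 (adjusted p of 0.102, 0.0939, 0.098 and 0.0891 in that order) and TYMS (0.0727, 0.078, 0.077 and 0.0635) missed the threshold as single genes.

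**Figure D2:**
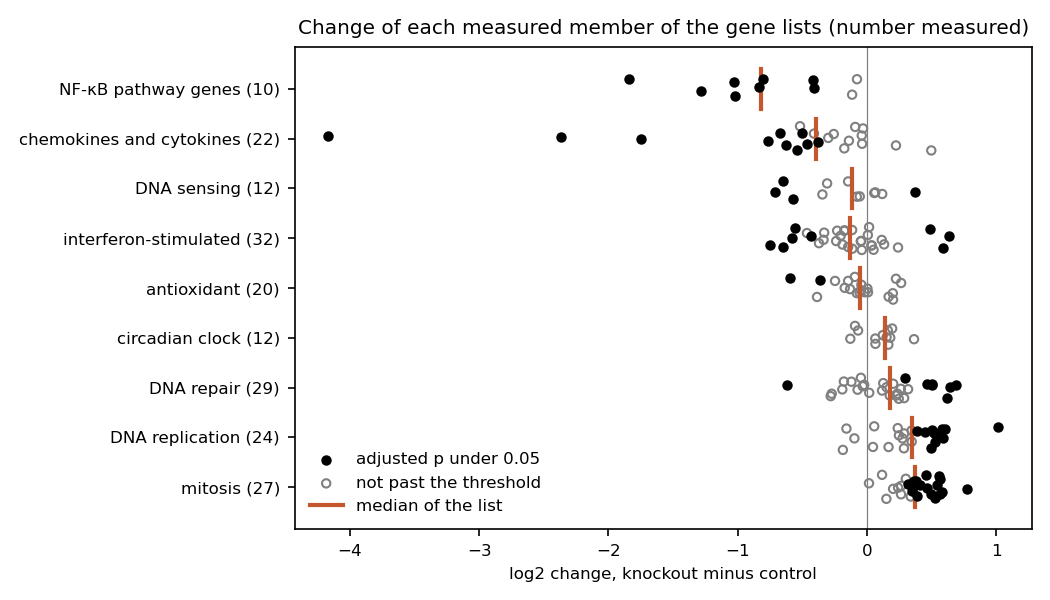
Log2 change (x axis, knockout minus control) of every measured member of 9 gene lists (y axis, number of members in brackets), with filled points for genes that passed an adjusted p of 0.05, open points for the others and a vertical bar at the median of the list. All 10 NF-κB pathway genes lie below 0 and all 27 mitosis genes above it.

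Genes of interferon signalling and DNA sensing went both ways. Of 32 measured interferon-stimulated genes 5 fell and 3 rose, or 7 and 4 when adjusted over the list alone. BST2, which encodes the antiviral tether tetherin, was 1.68-fold lower and OASL, of the oligoadenylate synthetase family, 1.57-fold lower, while the nuclear body gene SP110 was 1.55-fold higher and RSAD2, the antiviral gene viperin, 1.5-fold higher. The list was lower by camera (adjusted p = 0.0334), but not with an estimated correlation (adjusted p = 0.455), nor by fry, which asks whether its genes move one way on balance (adjusted p = 0.109). It also missed the threshold without control replicate 2 (adjusted p = 0.112) or knockout replicate 2 (adjusted p = 0.059). Of 12 DNA sensing genes 3 fell and 1 rose, or 5 and 1 when adjusted over the list alone. ENPP1, which encodes a hydrolase of the messenger cGAMP, was 1.64-fold lower, the inflammasome DNA sensor gene AIM2 1.57-fold lower and the RNA sensor gene TLR3 1.48-fold lower, and the helicase gene DDX41 was 1.29-fold higher. DDX41 missed the threshold without control replicate 1 (0.0649), 2 (0.0561) or 3 (0.0637) or knockout replicate 2 (0.0611). Of genes chosen after their values were seen, CGAS measured 8.97 ± 0.065 in control and 9.09 ± 0.074 in knockout arrays (adjusted p = 0.451), STING1 6.89 ± 0.083 and 6.58 ± 0.0788 (adjusted p = 0.0616) and the chemokine gene CCL5 6.66 ± 0.0957 and 6.25 ± 0.307 (adjusted p = 0.139, n = 3 each). The DNA sensing list was lower at an adjusted p of 0.0459 by camera and, unlike the interferon list, also by fry (adjusted p of 0.00205). It had an adjusted p = 0.222 with an estimated correlation, and missed the threshold without control replicate 1 (0.0556), 2 (0.051) or 3 (0.0659) or knockout replicate 1 (0.0839) or 3 (0.114).

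DNA repair genes were higher as a list. Of 29 measured 7 rose and 1 fell, or 10 and 2 when adjusted over the list alone. The rises were 3 without control replicate 1, control replicate 3 or knockout replicate 2, and 4 without knockout replicate 3. BRIP1, a helicase gene of the Fanconi anemia pathway, rose 1.61-fold, XRCC4, of non-homologous end joining, 1.57-fold and the DNA damage checkpoint gene MDC1 1.53-fold. The 8 probe sets of MDC1 changed by 0.609 to 0.645 on the log2 scale, but they read the same gene and give no independent support. NBN, a subunit gene of the double-strand break sensor complex, was 1.53-fold lower and lies on chromosome 8 within 85 neighbouring genes of which 71 measured below 0. The camera adjusted p was 0.0108, and the adjusted p = 0.222 with an estimated correlation. XRCC4 missed the threshold without control replicate 1 (0.0984) or 3 (0.0889) or knockout replicate 2 (0.099) or 3 (0.0886).

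Neither the circadian nor the antioxidant list was called. None of 12 measured circadian clock genes passed the limma test, over all genes or over the list alone, and 2 of them, RORA and NPAS2, are given here as those with the smallest p. RORA, which encodes an activating receptor that shares DNA elements with REV-ERBα, measured 4.40 ± 0.146 in control and 4.77 ± 0.0818 in knockout arrays (adjusted p = 0.0548), and NPAS2 8.93 ± 0.0319 and 9.09 ± 0.0373 (adjusted p = 0.243, n = 3 each). The clock list had a camera adjusted p of 0.187, with 9 genes above 0, 3 below and a median log2 change of 0.138. Of 20 antioxidant genes 2 fell and none rose, the same 2 when adjusted over the list alone. TXNRD1, which encodes thioredoxin reductase 1, was 1.51-fold lower, and HMOX1, of heme breakdown, 1.29-fold lower. HMOX1 missed the threshold without control replicate 1 (0.0557), 2 (0.107) or 3 (0.111) or knockout replicate 1 (0.0828) or 2 (0.0952). The antioxidant list had a camera adjusted p of 0.325, with 7 genes above 0 and 13 below. Only 12 of 18 clock genes and 20 of 41 antioxidant genes were measured, so these misses do not show that either list was unchanged.

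Some lists of metabolism and stress genes were called by camera with its preset correlation, and others, given further below, were not. Of 18 fatty acid metabolism genes 4 fell and none rose, or 5 and none when adjusted over the list alone, among them the acyl-CoA synthetase genes ACSL1 (2.37-fold lower) and ACSL4 (1.87-fold lower). The falls were 2 without any 1 control replicate or without knockout replicate 2 or 3. The camera adjusted p was 0.000374, and the adjusted p = 0.113 with an estimated correlation. Of 15 glycolysis and hypoxia genes 3 rose and none fell, the same 3 when adjusted over the list alone, with VEGFA, the vascular growth factor gene, 1.58-fold and the hexokinase gene HK2 1.47-fold higher (camera adjusted p of 0.0102, adjusted p = 0.159 with an estimated correlation). Of 17 genes of endoplasmic reticulum stress 4 fell and 1 rose, the same when adjusted over the list alone, but 1 fell and 1 rose without any 1 of the 6 arrays. ERN1, which encodes the stress sensor IRE1α, was 2.56-fold lower and the serine synthesis gene PSAT1 1.43-fold higher (camera adjusted p of 0.0107, adjusted p = 0.159 with an estimated correlation). Of 15 lysosome and autophagy genes 3 fell and none rose, or 5 and none when adjusted over the list alone, led by LAMP2 (1.83-fold lower), which lies on chromosome X within 102 neighbouring genes of which 86 measured below 0 (camera adjusted p of 0.0125, adjusted p = 0.222 with an estimated correlation). The falls of that list were 1 without any 1 control replicate. Of 12 p53 target genes 1 fell, or 4 when adjusted over the list alone, and this 1 was the stress cytokine gene GDF15, which was 2.67-fold lower. That list had a camera adjusted p of 0.0334 and an adjusted p = 0.203 with an estimated correlation, and missed the threshold without control replicate 2 (0.051) or knockout replicate 3 (0.0586).

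Of 7 antigen presentation genes 2 fell, or 4 lower and 1 higher when adjusted over the list alone, among them the peptidase gene ERAP1 (1.52-fold lower). The falls were 1 without any 1 control replicate or without knockout replicate 1 or 2. The camera adjusted p of that list was 0.0459, with an adjusted p = 0.222 under an estimated correlation, and it missed the threshold without control replicate 1 (0.0556), 2 (0.051) or 3 (0.0711) or knockout replicate 2 (0.059) or 3 (0.132). None of 20 ribosomal protein genes passed as a single gene, over all genes or when adjusted over the list alone, but 1 rose without knockout replicate 2. That list had a camera adjusted p of 0.0411 in the direction of a rise, an adjusted p = 0.268 with an estimated correlation and an adjusted p of 0.0548 by fry, and missed the threshold without control replicate 1 (0.0608) or 2 (0.0518) or knockout replicate 1 (0.175) or 3 (0.0604). Without control replicate 2 the number of lists called fell from 14 of 27 to 9.

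Extracellular matrix genes moved in both directions, with 4 of 15 higher and 4 lower, the same counts when adjusted over the list alone, and a camera adjusted p of 0.366. By fry the list passed in the direction of a rise, with an adjusted p of 0.0136. The falls were 1 without control replicate 1 or 3 or knockout replicate 2, and 2 without control replicate 2 or knockout replicate 1 or 3. The matrix glycoprotein gene TNC rose 2.96-fold, the collagenase gene MMP1 2.33-fold and the fibronectin gene FN1 1.78-fold, while the fibrillin gene FBN1 was 1.86-fold lower. TNC lies in the same stretch of chromosome 9 as TRAF1. Lists of other cell types were not called. None of 5 leukocyte marker genes, 6 fibroblast marker genes or 5 basal epithelial marker genes passed as single genes, over all genes or adjusted over the list alone, and the camera adjusted p was 0.562, 0.515 and 0.756. Of 7 endothelial markers 1 rose, KDR, a vascular growth factor receptor gene (1.42-fold higher), and 1 fell, the same when adjusted over the list alone, with a camera adjusted p of 0.484 and 0 falls without control replicate 3 or knockout replicate 2. Of 20 luminal epithelial markers 3 rose and 2 fell, or 3 and 4 when adjusted over the list alone, with the transcription factor gene GATA3 1.65-fold lower and a camera adjusted p of 0.834. Of these, 0 rose and 1 fell without any 1 control replicate or without knockout replicate 2 or 3. The lists of heme metabolism (camera adjusted p of 0.198), cholesterol synthesis (0.366), oxidative phosphorylation (0.666), heat shock (0.785) and mesenchymal genes (0.889) were not called either. In the heat shock and mesenchymal lists the median and the mean log2 change differed in sign.

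Changes were uneven along the genome. Windows of 20 neighbouring protein-coding genes departed from shuffled gene orders in 15 stretches with 693 of 11910 ordered genes. A stretch joins windows beyond the shuffled orders either as fitted (114 windows, beyond a mean of 0.36) or with each change bounded at 2-fold (307 windows, beyond 0.274). The longest runs were 98 genes on chromosome 1, from SLC71A1 to POLR3C, with 46 lower and none higher, and 102 genes on chromosome X, from DCX to ZFP92, with 36 lower and 1 higher. On chromosome 9, 58 genes from ZNF618 to ENG held 20 higher and 1 lower. Over whole chromosomes, 75 genes of chromosome 9 were higher and 5 lower (camera adjusted p of 2.15e-05). Chromosome X had 11 higher and 74 lower (camera adjusted p of 3.12e-05), and chromosome 6 had 98 higher and 22 lower (0.000121). Chromosome 21 had 4 higher and 12 lower (camera adjusted p of 0.00619). With an estimated correlation, chromosomes 9, X, 6 and 21 each had a camera adjusted p = 0.0449. Chromosomes 13, 14, 8 and 4 were lower with the preset correlation only (camera adjusted p of 0.000135, 0.0141, 0.0202 and 0.0408). Of the 20 genes with the largest changes 1 lay in such a stretch, CACHD1 on chromosome 1, which rose among neighbours of which 51 of 68 measured below 0. That count covers the stretches alone and does not say which of the 20 genes lie on a chromosome called as a whole.

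**Figure D3:**
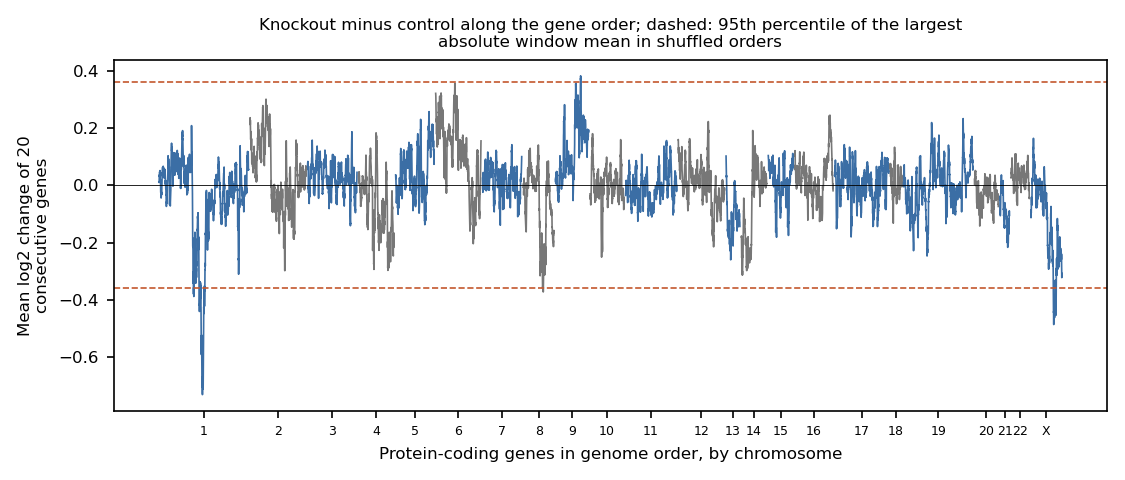
Mean log2 change (y axis, knockout minus control) of 20 consecutive measured protein-coding genes along the gene order (x axis, chromosomes in alternating colours). Dashed lines mark the 95th percentile of the largest absolute window mean in 1000 shuffled orders, 0.36, and the largest window, on chromosome 1, reached 0.732 below 0 (windows of changes bounded at 2-fold are not drawn).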

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

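The test of probe sets without a gene name was chosen after the main comparison had been seen. The 37519 such probe sets entered no test of genes or lists above, though the correlations between arrays included them. Among them, 451 passed an adjusted p of 0.05 between knockout and control arrays (limma with Benjamini-Hochberg adjustment over the unnamed probe sets), 189 higher and 262 lower. That is 1.2% of the unnamed probe sets against 9.49% of the named genes. Of the 451, 171 changed by 2-fold or more. The largest rises were at probe sets 16818440, from 2.49 ± 0.519 to 6.98 ± 0.255 (log2, mean ± SD, n = 3 each), and 16826110, from 2.93 ± 0.108 to 7.01 ± 0.298. The largest falls were at 17123952, from 8.62 ± 0.32 to 3.89 ± 0.457, and 16691090, from 6.23 ± 0.0336 to 3.18 ± 0.342.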

How the results depend on the processing

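The alternative without genes in stretches of neighbours that changed together was chosen after seeing the data; it called 1044 genes and 14 lists. The count of 1412 changed genes was 558 at 1.5-fold or more with an unadjusted p under 0.05 and 333 with limma's treat against 1.2-fold, which is stricter by construction. Leaving out 1 array gave 723 to 1049 changed genes, 336 to 518 higher and 387 to 531 lower. Testing every probe set on its own gave 1188 changed probe sets of 53617, and 539 of the 1412 genes kept their call. Changes of 2-fold or more were then 328 in place of 142. No rescaling moved the median change of all genes by over 0.1 on the log2 scale or the share of higher calls by over 10 percentage points.

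With an estimated correlation 2 lists remained of 14, and the others had adjusted p of 0.185 (mitosis), 0.159 (replication, endoplasmic reticulum stress, glycolysis and hypoxia), 0.113 (fatty acids), 0.222 (DNA repair, lysosome, antigen presentation, DNA sensing), 0.203 (p53), 0.268 (ribosomal proteins) and 0.455 (interferon). Without the dimmest 25% of genes antigen presentation, DNA sensing, interferon and ribosomal proteins each stood at 0.0536; without the dimmest 50% antigen presentation had 0.0632, DNA sensing 0.0695, ribosomal proteins 0.187 and endoplasmic reticulum stress 0.0539. Array weights gave 0.0622 for DNA sensing and 0.076 for ribosomal proteins, and fry 0.109 for interferon and 0.0548 for ribosomal proteins; extracellular matrix, not called before, passed by fry at 0.0136. Leaving out 1 array gave 9 to 12 called lists, with adjusted p of 0.0201 to 0.132 for antigen presentation, 0.0277 to 0.114 for DNA sensing, 0.0194 to 0.112 for interferon, 0.0241 to 0.0586 for p53 and 0.0135 to 0.175 for ribosomal proteins. Apart from the estimated correlation, the NF-κB, cytokine, mitosis, replication, fatty acid, DNA repair, glycolysis and lysosome lists kept their call and direction under every alternative run. The cause of these shifts was not tested.

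Direction turned, without a call, in the mesenchymal list (adjusted p of 0.98 after quantile normalization, 0.873 and 0.98 without the dimmest 25% and 50%, 0.747 to 0.943 without 1 array), the luminal list (0.98 without the dimmest 50%, 0.738 to 0.944 without 1 array), the basal list (0.61 to 0.955 without 1 array) and MSL1 (log2 change of -0.0192 to 0.185 without 1 array). Of 123 genes picked by the rule for named genes or after their values were seen, not all of which the text gives, 105 passed the threshold, 73 of them in every alternative that gave a value, and 32 missed it in at least 1.

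The replicate numbers are shared between groups but do not pair the arrays: deviations of same-numbered arrays correlated at 0.055, 0.068 and -0.11, and 2 of 6 arrays correlated best with their own number. With the replicate number as a block 1050 genes were called, 995 of them among the 1412, and 140 at 2-fold or more; no list call changed. With 3 arrays a group and no detection calls, signal over background could not be set for single genes.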

Other observations

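The genes and gene families in the next paragraphs, the tests of dim probe sets and of leukocyte RNA, and the fit without stretches of neighbours, were chosen only after the result was seen.

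Beside C3, some single genes of innate immunity outside the fixed lists were lower in the knockout. They were picked singly and not tested as a set, and of 10 genes whose names begin with TLR 2 were higher and 2 lower (camera adjusted p of 0.804). The complement genes C2 and CFB were 2.55-fold and 2.47-fold lower, the bacterial lipoprotein receptor gene TLR2 3.28-fold lower (from 8.66 ± 0.0793 to 6.95 ± 0.0414, log2, mean ± SD, n = 3 each), the acute phase gene SAA1 3.13-fold lower and the chemokine gene CXCL16 3.49-fold lower. The microRNA genes MIR146A and MIR3142, which share a locus, were 3.01-fold and 4.58-fold lower. The limma adjusted p was 0.0013 or below for these genes, and each was lower on all 3 knockout arrays than on any control array. The groups did not overlap for any of the 1412 called genes, so this adds no support.

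Beside DSG2, further genes of desmosomes were higher, with the linker gene DSP up 2.42-fold (from 8.28 ± 0.0833 to 9.55 ± 0.0397, n = 3 each), the cadherin gene DSC2 2.1-fold and the plaque gene PKP2 1.59-fold, but the plakoglobin gene JUP was 1.25-fold lower (adjusted p = 0.0328). JUP missed the threshold without control replicate 1 (0.103), 2 (0.101) or 3 (0.0932) or knockout replicate 1 (0.0733), 2 (0.1) or 3 (0.0544). These were picked singly and not tested as a set. Whether they lie in stretches of neighbours that changed together was not looked up. Their changes therefore cannot be taken as independent of such stretches or of each other. Of 160 families of genes that share a name stem, 7 passed a camera adjusted p of 0.05 with the preset correlation and 0 with an estimated one (adjusted p = 0.997). The lowest p belonged to the nucleoporin family, whose proteins build the nuclear pore, with 8 of 22 genes higher and none lower (adjusted p = 8.5e-05), among them NUP210 (2.09-fold), NUP188 (1.71-fold) and NUP160 (1.4-fold). NUP188 lies on chromosome 9, of which 75 genes were higher and 5 lower, so its rise went the way of that chromosome.

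The groups make 10 splits into 3 and 3 arrays, too few for a share under 0.05. For each of the counts, 1 split, the real one, reached the real value: 1412 changed genes against at most 0 in the others, 142 changed by 2-fold or more against at most 0, and 14 lists called against at most 5. Every other split mixes control and knockout arrays, so a difference between the groups widens its spread and keeps its counts low. The low counts of the other splits therefore lend no support.

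The fall of NF-κB and cytokine genes was not the work of 1 array, since the highest adjusted p of the lists over the fits without 1 array was 7.9e-08. Nor was it confined to dim probe sets. The 18 of 32 members with a mean over all arrays above that of the median gene had a median log2 change of -0.717. A 95% bootstrap interval over these genes ran from -1.16 to -0.419. It treats the genes as independent and holds no spread between arrays. A member can also count as bright through its control arrays alone, as CXCL8 did (8.38 in control, 4.21 in knockout). The labels name only cells of the MDA-MB-231 line, so leukocytes were not part of the design. The 5 leukocyte markers could not test for a loss of leukocyte RNA. They all lay below the level of the median gene in control arrays (4.95 to 6.08). Their lowest change, -0.294 on the log2 scale for CD14, could be held small by the array floor. Whether the fall comes from the loss of NR1D1, from differences between the cell populations that were compared or from the response to peroxide stays open, with no untreated arrays and an unknown number of clones.

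The rise of mitosis and replication genes was also not decided by 1 array (highest adjusted p over the fits without 1 array, 1.16e-07). The lowest knockout array mean lay above the highest control array mean by 0.263 for mitosis and by 0.199 for replication, against largest ranges within a group of 0.13 and 0.132. Since the labels do not say whether the arrays of a group came from separate cultures, these gaps leave differences in growth between cultures open. A candidate explanation is a larger share of dividing cells under peroxide in the knockout, which transcript levels alone do not measure. A difference in seeding density between the groups was not tested, and neither list passed with an estimated correlation between its genes (adjusted p = 0.185 and adjusted p = 0.159).

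Neighbouring genes changed together over long stretches, with the largest mean of 20 consecutive genes at an absolute log2 change of 0.732 against a 95th percentile of 0.36 in shuffled orders. Short clusters of co-regulated genes would not reach that far, since changes still correlated at 0.0946 between genes 20 places apart (shuffled 95th percentile 0.014). A technical trend that varies from array to array is argued against too: differences between arrays of 1 group correlated at no more than 0.00852 at that distance, and between groups at 0.0489 to 0.0924. Copy number differences between the knockout and the control cells, as when an aneuploid line is cloned, stay open: the window mean is the pattern itself, no DNA was measured, and a trend shared by all arrays of a group would look alike. CSF1 (-1.75) and TNC (1.56) changed by more than their stretches, which had medians of -0.264 and 0.254 and means of -0.451 and 0.271, and TRAF1 and CACHD1 went against theirs. The NF-κB and mitosis lists kept their camera calls at the preset correlation without these stretches (adjusted p of 6.7e-10 and 5.94e-15). Over all genes, mitosis had not passed camera with an estimated correlation (adjusted p = 0.185).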
